A study of Homo sapiens with 4 samples.

How the data were processed

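MIA PaCa-2 is an established human pancreatic cancer cell line. The cells carried a short hairpin RNA against MED30, a subunit of the Mediator coactivator complex, that doxycycline switches on. Per the labels, 2 libraries came from cells without doxycycline, called control here, and 2 from cells given 0.5 µg/ml doxycycline for 3 days. The assay was PRO-seq (precision nuclear run-on sequencing), in which polymerases already engaged on genes in isolated nuclei extend their RNA with biotin-labelled nucleotides. Its values measure transcription under way at a gene, not the amount of mature RNA. Drosophila S2 cells were added as a spike-in, with 50 human cells for each fly cell, per the labels. Each library had 1 table of human genes and 1 table of fly transcripts. Bowtie2, HOMER and DESeq2 and the builds hg38 and dm3 were named in the submitters' processing notes, without versions or roles. The gene model, the use of strand, filters and the treatment of reads with several positions are not given in the sources used here.

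The deposited human values were whole numbers per gene, but they behaved as a score that had been scaled and rounded, not as read counts. Between replicate libraries, the squared difference over the sum averaged 0.399 to 0.427 over genes whose sum was above 2 and up to 5, where raw reads would give about 1. The same ratio was 1.60 to 2.24 for sums above 1000 and up to 10000, so the replicates differed beyond the noise of low values and were kept as separate libraries. A search for 1 step per library gained 2.78 to 6.72 units of log-likelihood, against 65 to 215 in simulated reads scaled by 1 factor. The human read depth of a library could therefore not be recovered. The deposited fly values, a signal, were whole multiples of 1 step per library, worth 22.3 and 23.4 in the controls and 21.4 and 19.2 with doxycycline. Of the fly values worth fewer than 130 steps, 99.6 to 100% equalled a whole number of steps exactly after rounding. Dividing by the step gave whole numbers, which were taken as fly reads. Many of the small ones were even, as in a row with 18 and 12 in the controls and 2 and 2 with doxycycline. A step may therefore be less than 1 independent read, and the fly read numbers below may be too high. Distinct fly rows then held 1035980 and 1007134 reads in the controls and 1085025 and 1204213 with doxycycline, where a read can count for several overlapping transcripts.

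The design written before the data were examined assumed read counts and edgeR's quasi-likelihood test for human genes. As the unit was another, the main test was limma on log2(value + 1) after scaling by TMM, with a trend of the variance with level, over the 14715 genes with a mean value of at least 10. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The 2 planned results that need human reads per fly read, total human transcription and genes changed per spike-in, were not computed. Every change reported is relative to the other human genes of the same library, and a shift common to all genes would go unseen. Gene lists fixed before the data were examined, 25 in all, were tested with camera at a preset correlation of 0.01 and adjusted over the 25 lists. An alternative estimated the correlation of each list. Its test has only 2 residual degrees of freedom, so almost no list can pass, and its adjusted p says little about a single list. For fly reads, edgeR's quasi-likelihood test with TMM was used over 10204 distinct rows, out of 33989 transcript rows, of which 13570 with reads were distinct. Fly rows carry transcript identifiers that the tables used here do not pair with gene names.

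Genes were named by a rule fixed in advance. It took MED30 and MYC and the 10 largest rises and 10 largest falls among called genes with a mean value of at least 100, a symbol and the same sign in all 4 differences between a doxycycline and a control library. It also took the 4 members with the smallest p of each called list, of the MYC targets and of the Mediator subunits. Any other gene named was chosen after its values were seen, and some genes are not reported here. Of 25050 human rows, 24303 matched a current symbol in the RefSeq table of GRCh38.p14, 620 of them through an older symbol, and 747 did not match. Coordinates and lengths are from that table. For 11 rows the name had become a number, as happens to some symbols in a spreadsheet; they held 0.0820% of the values, stayed in the test and are not named. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

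The scripts were tested on simulated values for the same genes, with 200 changed genes in each of 5 runs of 14715 human genes. A 1.25-fold change was recovered in 59.5% of the genes given it, a 1.5-fold change in 86.9% and a 2-fold change in 96.8%, and 0.0193% of the unchanged genes were called. The simulated human reads were worth 0.4 each, with 1 extra spread shared by all genes. The search above found no such single step in the deposited values, and far more than 200 genes were called in them. These rates therefore check the scripts and need not hold for the deposited values. In 1 run of 10204 fly rows, a 2-fold change was recovered in 19.1% of the rows given it, a 4-fold change in 71.7%, and 0.0500% of the unchanged rows were called. A simulated shift of 1 list was called, and 0 of the other 24 lists were. In that run each gene was drawn independently and no other gene changed, so it does not check the preset correlation. With 2 against 2 libraries, an exact permutation test has 6 splits and a smallest two-sided p of 0.333, so no single value was tested in that way. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The alternatives were DESeq2, other filters, normalizations and fold thresholds, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were edgeR on the deposited human values, other pseudocounts, the values as deposited and a constant variance.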

Results

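Nascent transcription was measured by PRO-seq in MIA PaCa-2 pancreatic cancer cells in which doxycycline induces a short hairpin RNA against MED30. There were 2 control libraries without doxycycline and 2 libraries with 0.5 µg/ml doxycycline for 3 days. The deposited human values had a median of 32 and 33 in the controls and of 37 and 37 with doxycycline. Values above 0 were found for 18999 and 18959 genes in the controls and for 19099 and 19242 genes with doxycycline. The number of human reads behind these scaled values is unknown, so no counting interval is given. Over 9773 genes with a mean value of at least 100, the log2 difference between replicates had an SD of 0.11 in the controls and 0.12 with doxycycline. Between libraries of different groups it was 0.31 to 0.32.

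The series asks what MED30 does for transcription driven by MYC, a transcription factor that promotes cell growth. MYC (chromosome 8, 127735434 to 127742951 in GRCh38) fell 1.23-fold, from 2317 ± 117 in the controls to 1880 ± 51.3 with doxycycline (SD, n = 2 each; log2 -0.30, SE 0.044, adjusted p = 0.000689). MED30 itself (chromosome 8, 117520713 to 117540262) had a value of 48.4 ± 7.30 in the controls and 43.1 ± 2.17 with doxycycline (SD, n = 2 each). This difference did not pass the test (log2 -0.16, SE 0.15, adjusted p = 0.410), and its 95% confidence interval ran from 0.714 to 1.13 as a fold. A short hairpin RNA acts on the finished transcript, so the transcription of MED30 does not check the knockdown. Without control replicate 2, the MYC call was lost (log2 -0.26, adjusted p = 0.0503), and it was also lost in a test against a 1.5-fold change (adjusted p = 1).

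Genes with the largest falls included 3 metallothioneins, small proteins that bind zinc and other metals. MT1X (chromosome 16, 56682470 to 56684196) fell 3.78-fold, from 834 ± 20.8 to 220.2 ± 5.27 (SD, n = 2; log2 -1.92, SE 0.054, adjusted p = 2.04e-07). MT1E (chromosome 16, 56625781 to 56627112) fell 3.20-fold, from 1564 ± 9.89 to 488 ± 0.753, and MT2A (chromosome 16, 56608584 to 56609497) fell 2.52-fold, from 1668 ± 1.14 to 660.0 ± 3.89 (SD, n = 2, both at adjusted p = 2.04e-07). The zinc-finger transcription factor genes EGR4 (378 ± 24.3 to 126 ± 3.70) and EGR2 (214 ± 1.37 to 85.8 ± 0.834), both induced quickly by growth signals, fell 2.97-fold and 2.48-fold (SD, n = 2). Among these falls were 2 genes whose products act in ribosome assembly. RRP12 fell from 6016 ± 210 to 2482 ± 68.3 and EBNA1BP2 from 391 ± 0.737 to 146 ± 1.18 (SD, n = 2; log2 -1.28 and -1.42). TRMT12, now TYW2, an enzyme of tRNA modification, fell from 211 ± 8.51 to 85.8 ± 1.97 (log2 -1.29). The long noncoding RNA genes LINC00623 and LINC00473 fell from 208 ± 0.680 to 53.6 ± 4.29 and from 1268 ± 24.0 to 439 ± 0.725 (log2 -1.94 and -1.53).

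Among the largest rises, ARFGEF3 (chromosome 6, 138161939 to 138344663) rose 2.92-fold, from 86.7 ± 2.54 to 255 ± 7.32 (SD, n = 2; log2 1.55, SE 0.080, adjusted p = 3.99e-06). RIMKLA, which makes the neuropeptide N-acetylaspartylglutamate, rose 2.77-fold, from 91.8 ± 6.03 to 256 ± 3.81. CYFIP2, a subunit of the actin-regulating WAVE complex, rose 2.76-fold, from 134 ± 3.09 to 370 ± 2.23, and GLRA2, a glycine receptor subunit, rose 2.48-fold, from 86.7 ± 1.11 to 217 ± 7.38 (SD, n = 2). KIAA1755 rose 2.33-fold, from 214 ± 2.19 to 499 ± 4.28. The remaining members of this group were LOC101927314 (2.34-fold), ZSWIM5 (2.30-fold), RGS17 (2.30-fold), CAND1.11 (2.30-fold) and MRVI1, now IRAG1 (2.25-fold), with adjusted p from 6.07e-06 to 8.71e-05. Apart from RIMKLA and KIAA1755, the genes of this group were 120661 to 403332 bases long. They lay in the longest class of tested genes, of which 42.3% rose. Another gene overlapped ARFGEF3, CYFIP2, GLRA2, KIAA1755, LINC00623, LINC00473 and EBNA1BP2, as was so for 33.1% of tested genes, and metallothioneins have near-identical copies, so the share of each in its value is uncertain.

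**Figure D1:**
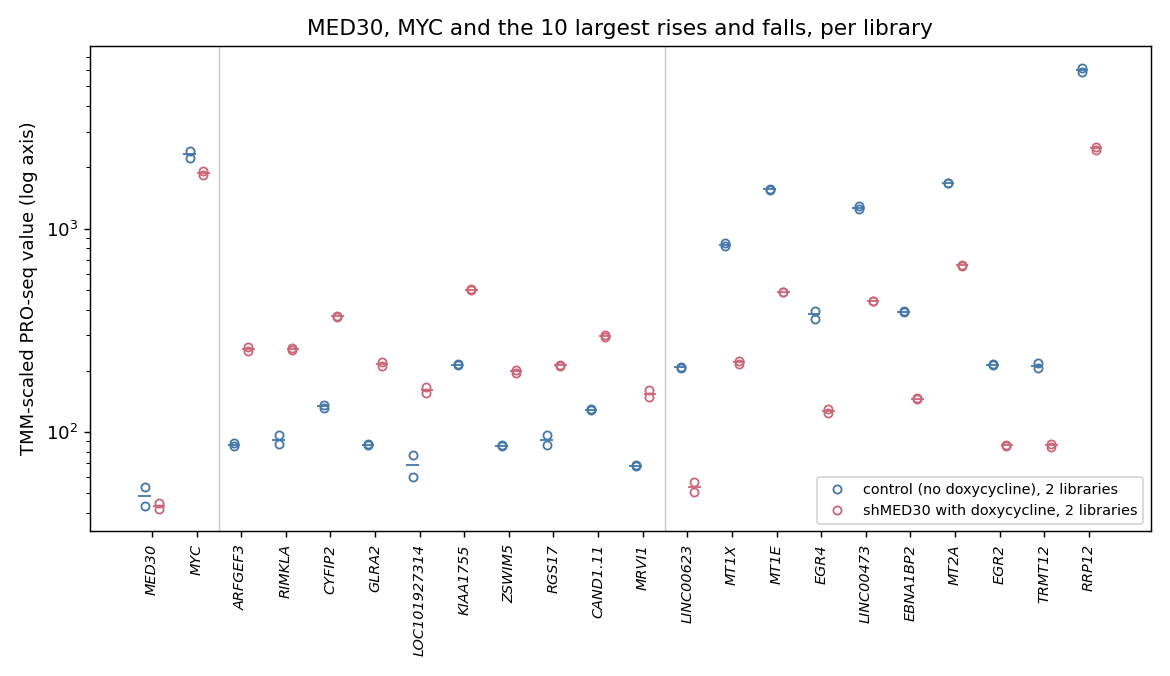
TMM-scaled PRO-seq values (vertical log axis, no unit) of MED30, MYC and the genes with the 10 largest rises and 10 largest falls, with a point for each library and a line at the mean of the 2 libraries of a group. MT1X lay at 834 in the controls and 220.2 with doxycycline, and ARFGEF3 at 86.7 and 255.

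In all, 6742 of 14715 tested genes (45.8%) changed with doxycycline, 3424 higher and 3318 lower. Most changes were small. The median absolute log2 change of the called genes was 0.37, 976 genes rose and 526 fell by over 1.5-fold, and 172 rose and 49 fell by over 2-fold. The 2 groups of libraries did not overlap at 73.8% of tested genes, where chance gives 33.3%. When scaled to the library totals in place of TMM, 4169 genes were higher and 2616 lower, 61.4% higher against 50.8%, and DESeq2 called 2262 genes. Without control replicate 1 or control replicate 2, 2484 and 2099 genes passed, and 117 passed a test against a 1.5-fold change.

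Genes for making proteins and dividing fell as groups. Of the 77 tested ribosomal protein genes, 65 fell, 1 rose (RPL13) and 11 did not pass, or 66 and 1 adjusted over the list alone, with a median log2 change of -0.44. RPL13 passed only narrowly by limma (adjusted p = 0.0489). Its deposited values were 2049 and 2242 in the controls and 2954 and 2305 with doxycycline. RPL24 fell from 749.7 ± 9.11 to 417 ± 28.0, RPS16 from 753 ± 9.83 to 451 ± 12.6 and RPL10 from 2027 ± 34.8 to 1323 ± 27.3 (SD, n = 2). Against the other genes, the list was lower by camera (adjusted p = 5.53e-19; adjusted p = 0.262 with an estimated correlation). The MYC target list held mainly nucleolar and growth genes that MYC binds and activates in many cell types, and was not drawn from these cells. Of 57 MYC targets, 37 fell, 3 rose (HK2, SLC29A2 and WDR74) and 17 did not pass, with the same counts adjusted over the list alone and a median of -0.31. Besides RRP12, the list held TBRG4 (1077 ± 41.7 to 600.5 ± 26.9), DUSP2 (449 ± 15.5 to 236 ± 1.04) and NPM1, a nucleolar chaperone (3157 ± 6.34 to 2228 ± 40.0; SD, n = 2), all lower. Camera placed the MYC targets below other genes (adjusted p = 1.04e-07, and adjusted p = 0.262 with an estimated correlation). The estimate for this list, -0.0093, was below the preset 0.01, so the lost call does not show correlation among its members. Estimates above the preset included 0.158 for ribosomal proteins, 0.255 for replication-dependent histones, 0.0906 for mitosis and 0.389 for immediate early genes. For such lists the p-values at the preset correlation may be too small.

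Of 36 tested replication-dependent histone genes, whose copies are near-identical, 31 fell and 3 rose, or 32 and 3 adjusted over the list alone, at a median of -0.52. HIST1H1D, now H1-3, fell from 449 ± 24.1 to 219.7 ± 13.7 and HIST1H4H, now H4C8, from 656 ± 4.49 to 343 ± 5.78, while HIST1H3J and HIST1H1E fell with log2 changes of -0.73 and -0.58 (SD, n = 2). The 3 that rose were HIST1H2BK, HIST2H2BE and HIST1H4I, the last from 17.1 ± 0.0615 to 54.1 ± 0.618 (adjusted p = 5.42e-05). HIST1H2AJ and HIST2H2AC did not pass. The list was lower by camera (adjusted p = 9.46e-12; adjusted p = 0.262 with an estimated correlation). In the mitosis list, 31 of 39 genes fell, 2 rose (CCNB2 and HMMR) and 6 did not pass, or 32 and 2 adjusted over the list alone, at a median of -0.37. The mitotic kinase gene AURKA fell from 1860 ± 59.4 to 1053 ± 1.88 and KIF23, a kinesin of cytokinesis, from 905 ± 3.17 to 511 ± 5.00, with CENPF and CCNB1 at -0.59 and -0.55 (SD, n = 2). Camera gave an adjusted p = 1.33e-10 for mitosis (adjusted p = 0.262 with an estimated correlation).

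Genes that respond to growth signals and to protein folding stress also fell. Of 31 immediate early genes, 24 fell, 0 rose and 7 did not pass, with the same counts adjusted over the list alone and a median of -0.42. KLF6 fell from 9661 ± 82.4 to 5215 ± 105, the orphan receptor gene NR4A3 (log2 -0.73), ZFP36, whose product destabilises mRNA, from 3390 ± 172 to 1788 ± 20.3 and the phosphatase gene DUSP1 from 3994 ± 47.1 to 2391 ± 97.7 (SD, n = 2). The camera result was an adjusted p = 4.07e-11 (adjusted p = 0.262 with an estimated correlation). Of 24 genes of the unfolded protein response, 16 fell, 0 rose and 8 did not pass, or 17 fell adjusted over the list alone, at a median of -0.35. The endoplasmic reticulum chaperone genes HSP90B1 and HSPA5 fell from 4867 ± 153 to 2008 ± 19.9 and from 3404 ± 52.9 to 1674 ± 64.0, CALR fell with a log2 change of -0.72, and HERPUD1, which acts in protein degradation at that organelle, fell from 3967 ± 3.54 to 1871 ± 43.6 (SD, n = 2). For this list camera gave an adjusted p = 7.42e-07 (adjusted p = 0.262 with an estimated correlation). In the heat shock list, 12 of 18 genes fell, 2 rose (HSPA4L and CRYAB) and 4 did not pass (DNAJB4, BAG3, CHORDC1 and HSF1), or 13 and 2 adjusted over the list alone, at a median of -0.30. DNAJB1, HSPA8, HSPH1 and DNAJA1 fell with log2 changes of -0.63, -0.62, -0.52 and -0.39, and the list had a camera adjusted p = 6.31e-05 (adjusted p = 0.262 with an estimated correlation).

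Of 23 NF-kB targets, 11 fell, 5 rose and 7 did not pass, with the same counts adjusted over the list alone and a median of -0.32. The falls included CXCL8 (660 ± 44.0 to 375 ± 0.578), which encodes a chemokine, PLAU, NFKBIA and CXCL2 (log2 -0.78, -0.78 and -0.76), and the rises were TNFAIP8, IL1A, TRAF1, LIF and TNIP1. The list was lower by camera (adjusted p = 0.0289; adjusted p = 0.262 with an estimated correlation). Of 26 autophagy and lysosome genes, 12 fell, 3 rose (ATG14, MCOLN1 and PSAP) and 11 did not pass, also adjusted over the list alone, at a median of -0.16, with GLA, a lysosomal galactosidase gene, from 2859 ± 8.12 to 1527 ± 1.65 and CTSA, ATP6V0D1 and SQSTM1 at -0.49, -0.45 and -0.41. Camera gave an adjusted p = 0.00290 (adjusted p = 0.262 with an estimated correlation). Of 49 genes of the respiratory chain and the mitochondrial ribosome, 16 fell, 2 rose (NDUFB3 and MRPS27) and 31 did not pass, or 15 and 2 adjusted over the list alone, with NDUFA1, NDUFA4, ATP5F1A and MRPL3 at -0.77, -0.71, -0.48 and -0.37. Its camera result was an adjusted p = 0.0142 (adjusted p = 0.262 with an estimated correlation).

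Of 17 genes often used as references, 10 fell, 2 rose and 5 did not pass (HPRT1, GUSB and B2M among them), or 11 and 2 adjusted over the list alone. ACTB fell from 3477 ± 1.07 to 2762 ± 127, YWHAZ fell with a log2 change of -0.49, and the rises were IPO8 and POLR2A, the largest subunit of RNA polymerase II, from 2937 ± 85.0 to 4860 ± 164 (SD, n = 2; log2 0.73). The list was lower by camera (adjusted p = 0.00907; adjusted p = 0.262 with an estimated correlation). Of 30 nucleotide synthesis genes, 10 fell, 2 rose (TYMS and DTYMK) and 18 did not pass, also adjusted over the list alone, with RRM2, a ribonucleotide reductase subunit, at -1.06 and NME1, NME2 and CTPS1 at -0.57, -0.52 and -0.48. Camera gave an adjusted p = 0.0367 (adjusted p = 0.393 with an estimated correlation). Of 39 DNA replication genes, 15 fell, 5 rose (GINS1, GINS4, POLA1, PRIM2 and CHAF1B) and 19 did not pass, also adjusted over the list alone. RFC3 and RFC2, subunits of the clamp loader, fell from 449.7 ± 4.09 to 219.7 ± 5.97 and from 885 ± 56.0 to 460.2 ± 18.9, with MCM3 and MCM7 at -0.57 and -0.37 (SD, n = 2), and camera gave an adjusted p = 0.0367 (adjusted p = 0.262 with an estimated correlation). Of 26 p53 targets, 11 fell, 3 rose (CDKN1A, TP53I3 and DDB2) and 12 did not pass, or 13 and 3 adjusted over the list alone, with PPM1D, TIGAR, TNFRSF10B and DDB2 at -0.34, -0.32, -0.27 and 0.28. The camera result for them was an adjusted p = 0.0367 (adjusted p = 0.262 with an estimated correlation). With a minimum mean value of 100, the nucleotide synthesis, DNA replication, p53, mitochondrial and NF-kB lists no longer passed (adjusted p from 0.127 to 0.205). Without doxycycline replicate 2, the first 4 of these and the acinar markers did not pass (adjusted p from 0.0690 to 0.0804), nor did nucleotide synthesis without control replicate 1 (0.0580) or p53 targets without doxycycline replicate 1 (0.127).

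**Figure D2:**
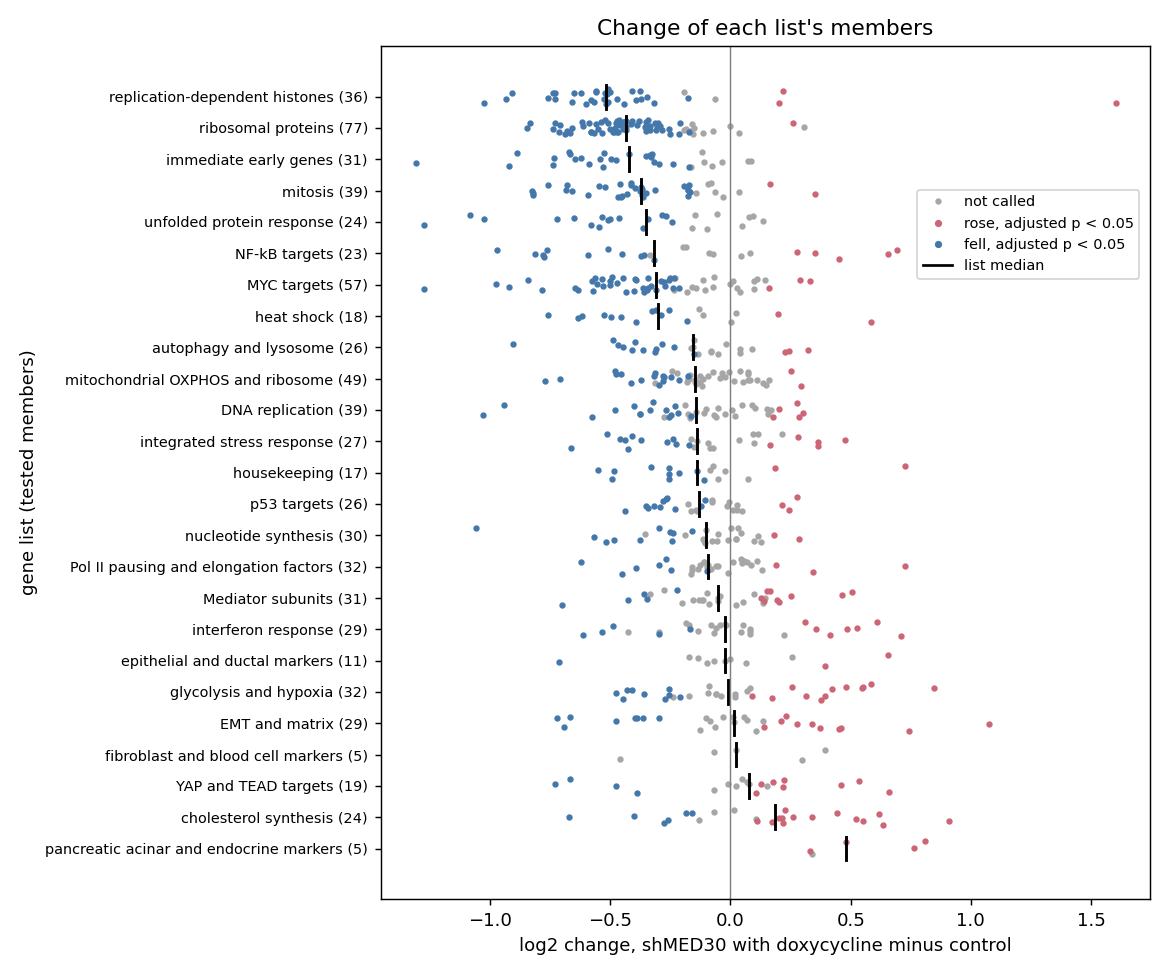
Log2 change of each tested gene (horizontal axis, doxycycline minus control) in the 25 gene lists, with the number of tested members in parentheses, a point for each gene coloured by its call and a black line at the list median. The medians of the replication-dependent histones and of the ribosomal proteins lay at -0.52 and -0.44, and that of the cholesterol synthesis genes at 0.19.

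Mediator subunits other than MED30 moved both ways. Of 31 tested, 9 rose, 5 fell (MED7, MED17, MED25, MED29 and MED31) and 17 did not pass, or 9 and 6 adjusted over the list alone, and the list did not differ from other genes by camera (adjusted p = 0.913). CDK19, a kinase of the Mediator kinase module, rose from 1164 ± 30.6 to 1651 ± 25.5 and MED12L from 240.0 ± 19.4 to 331 ± 7.90, while MED25 fell from 595 ± 37.8 to 365 ± 13.2 and MED31 from 634 ± 6.99 to 498 ± 3.44 (SD, n = 2). Among 32 tested factors of polymerase II pausing and elongation, 3 rose (POLR2A, AFF1 and NELFA) and 7 fell, also adjusted over the list alone, including SUPT5H (log2 -0.45) and SUPT4H1 (log2 -0.62), which form the elongation factor DSIF (camera adjusted p = 0.283). Other lists had no call by camera. Cholesterol synthesis had 14 rises and 6 falls of 24, also adjusted over the list alone (adjusted p = 0.0525). The integrated stress response had 5 rises (PHGDH, SLC7A11, SLC7A5, VLDLR and ALDH1L2) and 11 falls of 27, or 5 and 14 adjusted over the list alone (adjusted p = 0.0564). There were 8 rises and 4 falls (CCN1, CCN2, LATS2 and GADD45B) among 19 YAP and TEAD targets (adjusted p = 0.530), and 7 rises and 5 falls (ISG15, IFIH1, STAT2 and IRF1 among them) among 29 interferon response genes (adjusted p = 0.913), with the same counts adjusted over the list alone. Glycolysis and hypoxia had 12 rises and 9 falls of 32, also adjusted over the list alone (adjusted p = 0.913). The medians of the glycolysis and interferon lists were -0.01 and -0.02, while their means, 0.04 and 0.01, and the test pointed up. The EMT and matrix list had 10 rises and 8 falls of 29, or 11 and 9 adjusted over the list alone (adjusted p = 0.983), where the test pointed down but the median and the mean were both 0.01.

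The remaining lists held markers of cell types. Of 18 acinar and endocrine pancreas markers, 5 were tested, and the median value over all 18 was 0 in every library. CPA1 rose from 41.3 ± 1.57 to 70.9 ± 4.80 and CELA2A from 24.2 ± 0.0868 to 43.1 ± 0.768, CTRB2 and CEL rose with log2 changes of 0.48 and 0.33, and CTRB1 did not pass, or 5 rose adjusted over the list alone (SD, n = 2). The list was higher by camera (adjusted p = 0.0297; adjusted p = 0.262 with an estimated correlation). The fibroblast and blood cell list had 5 tested members (CD79A, CD14, CD68, VWF and SPI1), of which 0 passed, also adjusted over the list alone (camera adjusted p = 0.913). Over all 20 genes of that list the median value was 2 to 3, and CD68 was highest at 167 to 194. Of 11 epithelial and ductal markers, KRT8 and CLDN18 rose, KRT19 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.913); the test and the median (-0.02) pointed down and the mean (0.01) up. CEL no longer passed when any 1 library was left out (adjusted p from 0.0905 to 0.153), and CTRB2 passed only without doxycycline replicate 1 (0.0159).

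Changes differed with gene length and level. Of the longest genes (86.6 to 2220 kb), 42.3% rose and 12.1% fell, and of the shortest (0.048 to 8.21 kb), 11.2% rose and 25.4% fell. Genes called higher had a median length of 51.9 kb and genes called lower one of 23.6 kb. Of the genes with the highest values (636 to 21020) 25.6% rose and 36.4% fell, and of those with the lowest (9.96 to 48.8) 21.3% rose and 7.71% fell. Across genes, which are not independent replicates, the Spearman correlation of log2 change with length was 0.221, and it was 0.275 to 0.483 within 5 equal classes of level.

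**Figure D3:**
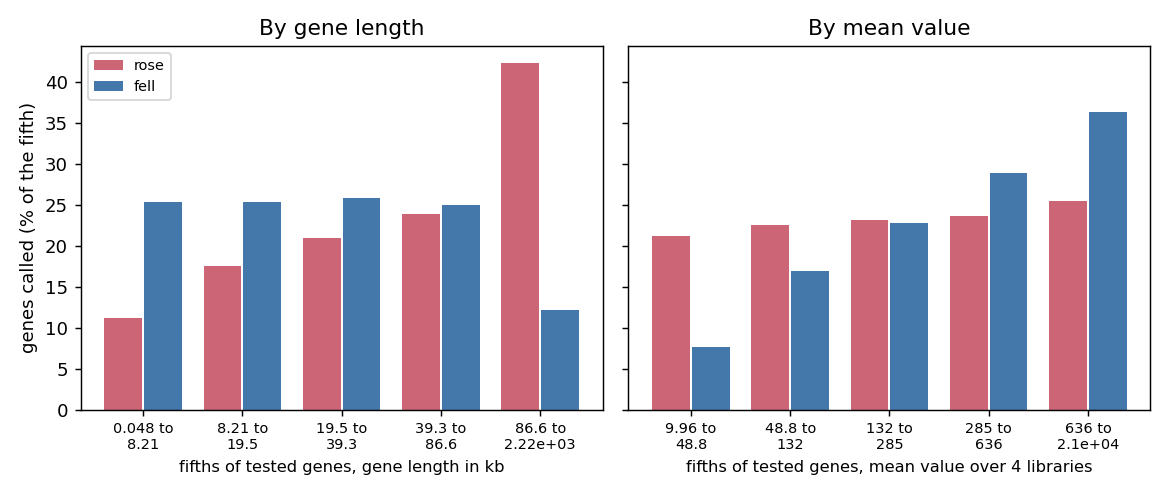
Share of tested genes called higher or lower with doxycycline (vertical axis, percent of the genes in each class) by 5 equal classes of gene length in kb (left) and of mean value over the 4 libraries (right), with 1 bar for genes that rose and 1 for genes that fell. The share that rose was 11.2% in the shortest and 42.3% in the longest class.

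The fly cells, added as a spike-in, gave a comparison between the same libraries, by edgeR on values taken as reads where human genes had limma on scaled values. The shares called are thus not on the same footing. Of 10204 fly rows, 25 (0.245%) were called by edgeR, 2 higher and 23 lower with doxycycline, and DESeq2 called 34. Some called rows held nearly the same reads, such as 2 with about 18130 and 18190 in control replicate 1 and 17620 and 17660 in doxycycline replicate 1. The 25 rows are therefore not 25 separate changes. At an unadjusted p under 0.05 by edgeR there were 565 of 10204 fly rows, where chance alone gives a share of about 0.05. Over fly rows the log2 differences between any 2 libraries had an SD of 0.72 to 0.81, and in simulated fly reads 19.1% of the 2-fold changes were recovered, so most changes of that size would go unseen. The count of called rows fell to 3 without doxycycline replicate 1 and to 10 without doxycycline replicate 2.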

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

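The tests chosen after the data were seen were edgeR on the deposited human values, pseudocounts of 0.5 and 5, the values as deposited and a constant variance. No called gene changed sign in a setting that tested it. MED30 stayed below the threshold in all that tested it, at log2 -0.32 to -0.01 with 1 library left out. The count of 6742 changed genes (3424 higher, 3318 lower) became 2262 (966 and 1296) with DESeq2, which takes the scaled values as counts, and 117 (52 and 65) against a 1.5-fold change, which asks for more than any change. With 1 library left out, where the lone library of a group is assumed to vary like the others, it was 2099 to 5924 (1022 to 3036 and 1077 to 2888). The labels do not say whether libraries with the same replicate number were paired. Their deviations correlated at 0.200 across genes, a single value, since with 2 libraries a group both pairs give the same one. The replicate block gave 8370 changed genes, keeping all 6742, and 7 fly rows in place of 25. A shared batch was therefore neither shown nor excluded. Without 1 library, 3 to 22 fly rows passed. Of 15 called lists, 0 were called with an estimated correlation, which leaves 2 libraries a group to estimate it. In that setting the test itself has only 2 residual degrees of freedom, whatever the estimate, so almost no list can pass. The adjusted p was 0.262 for 14 lists and 0.393 for nucleotide synthesis, the highest over the alternatives of each. It was 0.262 where the estimate was above the preset 0.01, as for immediate early genes (0.389) and ribosomal proteins (0.158). It was also 0.262 where the estimate was below the preset, as for MYC targets (-0.0093), the unfolded protein response (-0.0388) and heat shock (-0.0438). Losing a call with this setting therefore does not show correlation within that list. With a mean value of at least 100, which tests fewer genes, 9 were called; nucleotide synthesis, DNA replication and mitochondrial genes had 0.150, p53 targets 0.205 and NF-kB targets 0.127, while the Mediator subunits (0.663) and the EMT and matrix list (0.987, and 0.974 with the values as deposited) turned direction without a call. With fry, which does not compare a list with other genes, the integrated stress response (0.0145), cholesterol synthesis (0.0246) and the interferon response (0.00459) passed, and cholesterol synthesis also with the replicate block (0.0462). With 1 library left out, 10 to 15 lists were called, and adjusted p ranged over 0.0207 to 0.0804 for nucleotide synthesis, 0.0217 to 0.0690 for DNA replication, 0.0317 to 0.127 for p53 targets, 0.00590 to 0.0715 for mitochondrial genes, 0.0168 to 0.0715 for acinar and endocrine markers, 0.0476 to 0.140 for the integrated stress response and 0.0207 to 0.0984 for cholesterol synthesis. Lists without a call whose direction turned in some of these fits ranged over 0.602 to 0.971 (glycolysis and hypoxia), 0.736 to 0.971 (EMT and matrix), 0.371 to 0.977 (YAP and TEAD targets), 0.853 to 0.977 (epithelial and ductal markers) and 0.697 to 0.971 (fibroblast and blood cell markers). Beyond what these constructions show, the cause was not tested. Other counts and list calls kept their side of the threshold, and the block changed no other call. The 2 planned spike-in results and all their alternatives, the spike-in scaling of MED30 and of the named genes, and prior counts, which became pseudocounts, were not run, since the human reads per library could not be recovered. This also limits depth: small changes of genes with low values are the least certain.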

Other observations

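The tests of background, of the metallothionein genes and of reads at gene starts, and the members named in the next paragraph, were chosen after the result was seen. The tests of matched lists were set before their own result, for the 7 lists with the smallest p only. Those 7 lists were picked by camera on the same data, so their low percentiles are not independent of the camera calls.

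Lists without a call as a group held genes that moved clearly and apart. In cholesterol synthesis, SC5D and MVD rose (log2 0.91 and 0.64), while INSIG1, which holds back the transcription factor SREBP2, fell from 4951 to 3109 (log2 -0.67, adjusted p = 2.25e-06). In glycolysis and hypoxia, PFKFB4 and P4HA1 rose (582 to 1048 and 1767 to 2649), while LDHA and SLC2A3 fell (4260 to 3063 and 4104 to 3093). In the EMT and matrix list, the intermediate filament gene VIM fell from 7202 to 4368 and the integrin gene ITGB1 from 9241 to 7018, while COL6A3 and ACTA2 rose (log2 0.46 and 0.74). These are means of 2 libraries, each called by limma.

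The first pattern was the fall of whole lists, and the technical explanation weighed was that short genes with high values fell in general. The median log2 change of each list was set against 10000 random lists of the same size. These were matched on 10 classes of level, the mean over the 4 libraries, and 5 classes of length. Its percentile was 0 for ribosomal proteins, 0 for histones, 0 for mitosis and 0 for MYC targets. It was 0.100 for immediate early genes, 0.0200 for the unfolded protein response and 1.84 for heat shock. Level and length, as far as these classes match them, did not account for the whole of these falls. Differences within a class were not removed. The shortest class ran from 0.048 to 8.21 kb, while the median length was 0.49 kb for histones, 5.01 kb for ribosomal proteins and 5.27 kb for immediate early genes. A part was shared with genes alike in level and length, as the matched lists had medians of -0.19 for ribosomal proteins, -0.23 for histones, -0.21 for immediate early genes, -0.15 for heat shock and -0.06 to -0.09 for the other 3. Of the other lists, NF-kB targets (0.0200), DNA replication (0.780) and mitochondrial genes (2.37) lay below the matched range and acinar markers (99.2) and cholesterol synthesis (100) above it, while for housekeeping (47.5), autophagy (8.41), nucleotide synthesis (18.2) and p53 targets (17.7) level and length may account for the change, and lower MED30 was not tested apart from doxycycline.

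The second pattern was the rise of long genes. A uniform background of reads would add the same value per kb to every gene. The median gain of all 2867 longest tested genes, called or not, was 0.0971 to 0.160 per kb over the 4 pairs of a doxycycline and a control library, while 4085 near-silent genes pooled gained 0.00382 to 0.00478 per kb, which argues against such a background as the whole cause. A shift of polymerases from gene starts into gene bodies, as with faster release from pausing, could raise long genes more than short ones. The correlation of log2 change with length was 0.483 across genes of the highest level, but values by position along genes were not analysed here, so this stays open.

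The third pattern was the fall of the metallothionein genes. The summed value of all 13 metallothionein copies in the tables fell from 4336 and 4283 in the controls to 1445 and 1430 with doxycycline (log2 -1.58), which argues against reads that only moved between near-identical copies, while which copies fell stays open. Of 11 genes that MTF1 activates, 6 were tested and all 6 fell, but 5 of these are metallothioneins, among them MT1A and MT1L (log2 -2.09 and -1.69), so the tally in part restates the pattern; the sixth was the zinc exporter gene SLC30A1 (168 to 79.8, log2 -1.07, adjusted p = 3.12e-05). SLC39A10, which MTF1 represses, fell too (3456 to 2813, log2 -0.30, adjusted p = 0.000214), against lower MTF1 activity as the only change. With 6742 genes called in all, other changes were known beforehand, so this says little about MTF1. Lower MTF1 activity as a part of the fall stays open. Doxycycline binds metal ions and could lower free zinc by itself, and with 0 libraries that had doxycycline without the short hairpin RNA, doxycycline itself and loss of MED30 cannot be told apart.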
